A study of Propionibacterium freudenreichii subsp. shermanii with 39 samples.

How the data were processed

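RNA from 6 *P. freudenreichii* strains, in growth at 30 °C and after 3 days at 4 °C, was hybridised to 1-colour Agilent arrays of 15744 features, 536 of them controls and 15208 probes of 45 to 60 bases. Per the file headers, the scanner files were made with Agilent Feature Extraction 10.5.1.1, while the submitters' processing notes name Agilent Feature Extraction 9.1. The processed signal is a fluorescence intensity on a linear scale, with spatial and multiplicative detrending on and local background correction off, per the file headers. The mean, median and background signals used beside it are also intensity values, per the file headers. The value table deposited by the authors holds log2 values. Its columns had medians between 7.35 and 7.38 and correlated with the log2 median signal of the same array with r between 0.88 and 1.00, so its scale is log2 and its columns share one level. How the authors reached that level is not given in the sources used here. Each group was planned with 3 separate biological experiments per the labels, and 2 RNA samples that the study had set aside were not analysed here.

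From each array, log2 of the processed signal was taken and the array's 75th percentile over all probes subtracted, since at least 81.5% of the probes were well above background on every array. Spots marked as outliers were left out (340 over 39 arrays). Only 3 spots were saturated. The 5 technical repeat arrays were averaged with the first array of the same RNA. The SD over regions of the difference between a repeat and its first array was 0.27 to 0.42 log2 units, against 0.29 to 2.02 between replicates of a group. Of 32 replicate pairs, 5 differed by no more than the least similar technical repeat. The labels call them separate experiments, no files were identical, and each was counted as 1 sample.

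The files pair no probe with a gene (0 of 15208), and the reference table of 2363 genes, of the assembly ASM94084v1, holds no sequences, so 0 probes could be named. Gene lists fixed before the data were examined and the set tests planned on them could therefore not be run. In place of genes, probes on the same strand that shared at least 25 consecutive bases were joined into 7308 target regions, 3350 of them with 1 probe, and the median over a region's probes was used. This unit was chosen after the probe sequences were seen. A gene can hold several regions, so counts of regions are not counts of genes. A region was tested if at least 1 of its probes was well above background on every array of at least 1 of the 12 groups, which left 7184. The rule for named features, fixed before the data were examined, needed a gene product. Its first part was kept without the product: the regions with the largest mean rise and fall among those that passed and had the same sign in all 6 strains (3336 regions), of which 2 that rose and 2 that fell are named.

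Tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on 12 group means over all 34 RNA samples, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The contrasts were the cold response averaged over the 6 strains, the response in each strain, the difference of responses among strains (F test) and the difference of levels among strains at each temperature (F tests). Tables and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The fits were tested on simulated data, with noise of each region's own spread over 7184 regions, of which 50 were changed at each of 4 sizes. For the mean of 6 strains, 34% of changes of 0.5 log2 units, 74% of changes of 1, 98% of changes of 2 and all 50 changes of 3 were recovered, with 7 unchanged regions called. For a single strain, CIRM-BIA9, 8% of changes of 1 and 72% of changes of 2 were recovered. Far fewer regions were changed there than passed in the real samples, and the noise was alike in every group. The adjustment was therefore stricter, and these rates do not carry over to the real fits.

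Alternatives chosen before the data were examined were normexp background correction with an offset of 50, quantile normalisation, the authors' values, no filter or a stricter filter on dim probes, the mean over probes, the repeat arrays left out, slide as a block, a replicate block, each strain fitted by itself, and each RNA sample left out in turn. Chosen after the data were seen were each probe by itself, the array median in place of the 75th percentile, the fits without the 5 bright cold samples, and the arrays of each slide by itself against regions called from the other slides. Pairing by sample number was not used in the main fit. Of 16 same-numbered growth and cold samples of a strain, 5 had deviations from their group means that correlated above 0.1. The r ran from -0.44 to 0.32, and both pairs of CIRM-BIA123 were above the limit (0.32 and 0.28). With so few samples per group, such deviations cannot exclude pairing.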

Results

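The transcriptome of *Propionibacterium freudenreichii*, a bacterium used to ripen Swiss-type cheese, was measured with 1-colour Agilent oligonucleotide arrays in 6 strains. These were CIRM-BIA482, CIRM-BIA472 and CIRM-BIA9, together with CIRM-BIA123, CIRM-BIA122 and CIRM-BIA118. Each strain was sampled in exponential growth at 30 °C after 20 h and again after 3 days at 4 °C. The 39 arrays held 34 RNA samples, 17 from growth and 17 from the cold, because 5 RNA samples were hybridised again as technical repeats. Each strain had 3 RNA samples per condition, except CIRM-BIA122 in growth and CIRM-BIA123 in the cold, which had 2 each after the study had set aside 1 aberrant sample of each. Between 81.5% and 99.0% of the 15208 probes were well above background on an array. The number of arrays limits the precision of every value below. The cold samples had also reached a later stage of the culture than the growth samples, so temperature and growth stage changed together in each comparison.

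The files give each probe a number and a sequence but no gene, so the probes were joined by shared sequence into 7308 target regions, of which 7184 were measured well enough to be tested. The regions are given by the identifier of their first probe, and none of the changes below is assigned to a gene.

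On 5 cold arrays the probe signals were bright and compressed. Their median signal lay between 279 and 985, against 40.8 to 188 on the other 34 arrays, and their median minus 75th percentile was -0.94 to -0.52 log2 units, against -1.98 to -1.49 elsewhere. These arrays were replicates 1 and 3 of CIRM-BIA9, replicates 1 and 2 of CIRM-BIA472 and replicate 3 of CIRM-BIA118. Counts are therefore also given without these 5 samples, a choice made after the data were seen.

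**Figure D1:**
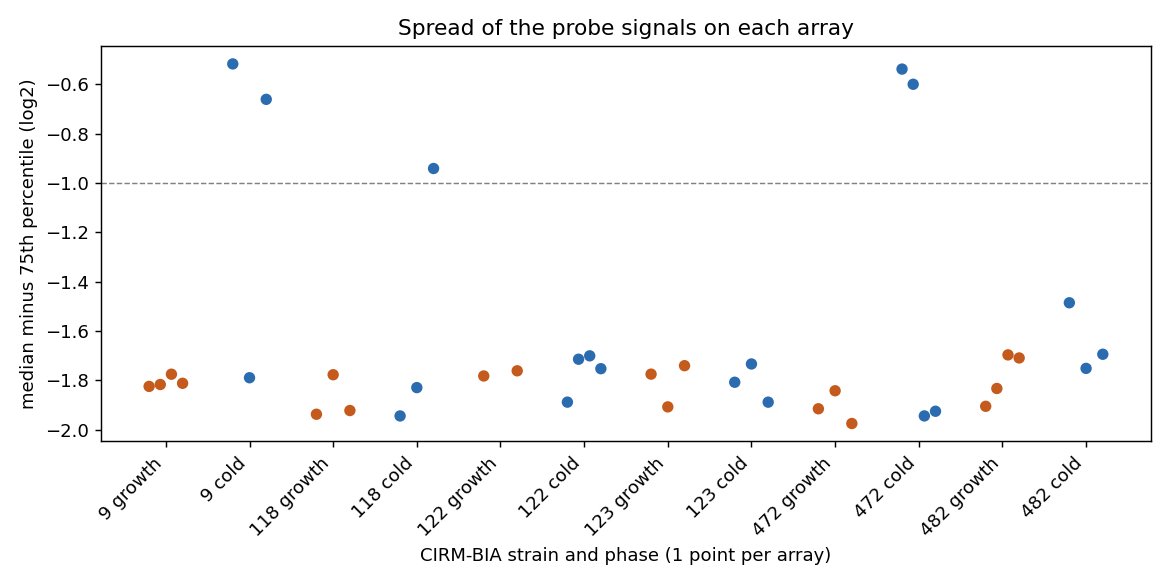
Median minus 75th percentile of the log2 probe signal for each of the 39 arrays (points), by strain and phase (orange, growth at 30 °C, blue, 3 days at 4 °C). The dashed line at -1 separates 5 cold arrays from the other 34.

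The first comparison asked which transcripts differ between cold storage and growth over the 6 strains. The region PFrdii_00185310 rose by 3.95 log2 units on average (SE 0.22, 15.5-fold, limma adjusted p = 4.26e-14) and passed the test in each of the 6 strains, with changes from 2.86 to 5.60. It rose by 2.81 with normexp background correction, by 3.31 in the authors' values and by 4.28 without the 5 bright samples. Its first probe is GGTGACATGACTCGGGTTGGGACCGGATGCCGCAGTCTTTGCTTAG. The region PFrdii_00179079 fell by 5.17 log2 units (SE 0.23, 36.1-fold, limma adjusted p = 3.86e-16), and PFrdii_00041869 fell by 4.83 (SE 0.22, 28.4-fold, limma adjusted p = 1.15e-15). Both passed in all 6 strains. With normexp background correction the mean change was -4.29 for PFrdii_00179079 and -4.22 for PFrdii_00041869. With quantile normalisation the mean changes of these 2 regions were larger, -5.59 and -5.11. Their first probes are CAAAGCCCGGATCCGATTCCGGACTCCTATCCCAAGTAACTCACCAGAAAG and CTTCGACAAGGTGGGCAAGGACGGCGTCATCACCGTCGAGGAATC, in that order.

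The region PFrdii_00197342 (first probe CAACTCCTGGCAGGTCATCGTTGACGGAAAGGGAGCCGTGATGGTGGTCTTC) had a fitted mean rise of 4.05 log2 units (SE 0.33, limma adjusted p = 5.51e-11). It was not well above background on any growth array of CIRM-BIA123 or CIRM-BIA472, so only a bound can be given there. It was at least 4.00-fold higher in the cold in CIRM-BIA123 and at least 39.3-fold higher in CIRM-BIA472, or at least 17.1-fold higher there by the 1 cold sample that was not bright. The fitted changes there passed (limma adjusted p = 0.0204 and 2.88e-07). They rest on growth signals not well above background, so these p-values do not test the bounds. These bounds set the mean of the cold samples against the higher of the region's own signal and the dimmest probe well above background on each growth array. In CIRM-BIA118 it was well above background on 1 of 3 growth arrays, and in CIRM-BIA9 and CIRM-BIA482 on 2 of 4. In CIRM-BIA122 the change of 2.17 (SE 0.87) did not pass (limma adjusted p = 0.0698). Its mean change was 3.36 without the 5 bright samples and 1.44 after normexp background correction.

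**Figure D2:**
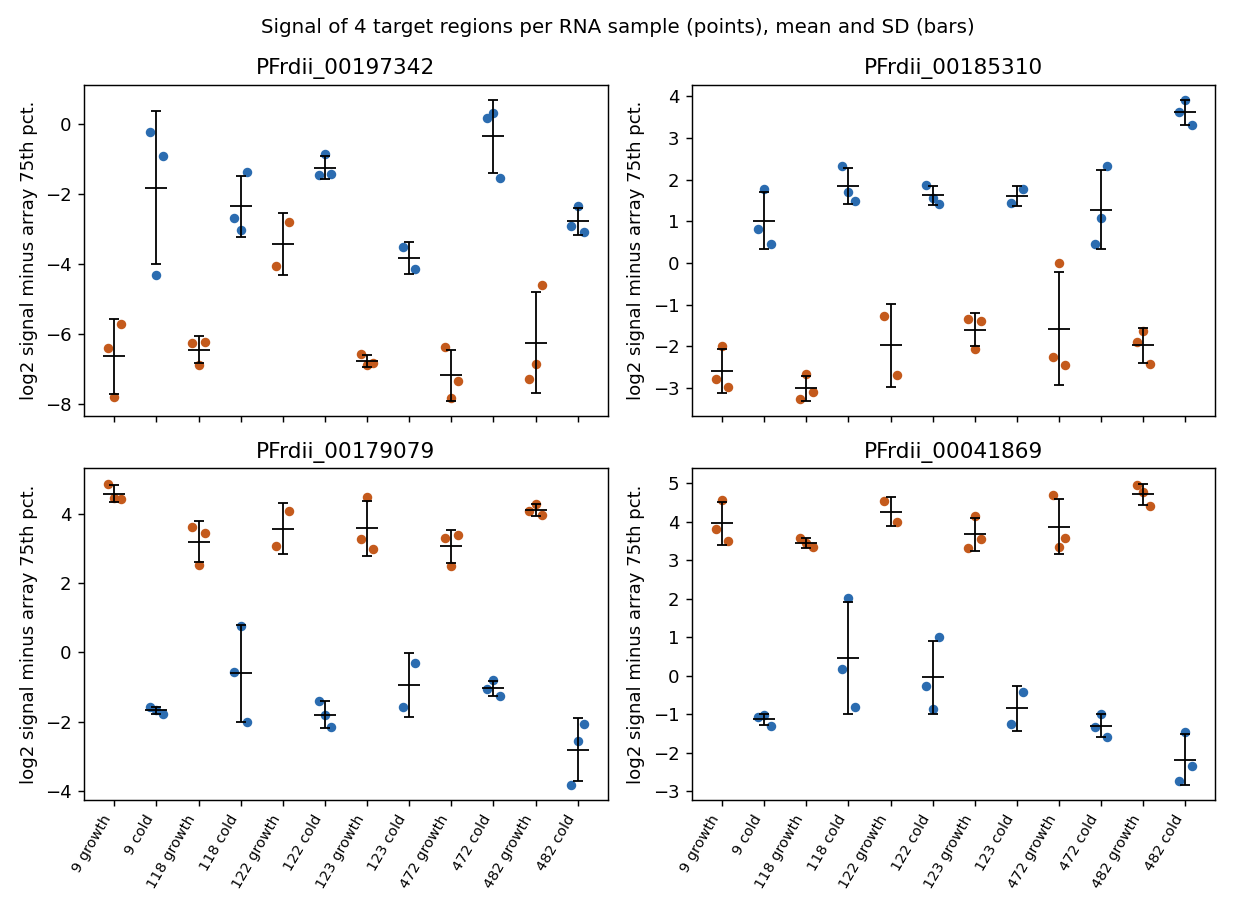
Log2 signal minus the array's 75th percentile of 4 target regions in each RNA sample (points), with the group mean and SD (black bars), by CIRM-BIA strain and phase (orange, growth at 30 °C, blue, 3 days at 4 °C). PFrdii_00185310 was higher in the cold in every strain, with changes from 2.86 to 5.60, and PFrdii_00179079 was lower in every strain.

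Over all regions, 5419 of 7184 passed the test of the mean response (limma, two-sided, Benjamini-Hochberg), 3662 higher and 1757 lower in the cold. Of these, 2103 rose and 934 fell by at least 2-fold. That balance depended on the processing: 1283 rose and 1386 fell by at least 2-fold with the array median, 1140 and 1265 with quantile normalisation, 619 and 833 in the authors' values, and 527 and 630 with normexp background correction. Without the 5 bright samples 1281 rose and 1167 fell by at least 2-fold. Without the 5 bright samples 5558 passed, 3262 higher and 2296 lower, and 4643 regions passed in the same direction in both. None passed in opposite directions. The size of the excess of rises over all regions that passed depended on the scaling as well. The median change over all tested regions was 0.46 log2 units with the 75th percentile, 0.10 with the array median and 0.07 with quantile normalisation. With the array median 2740 regions rose and 2400 fell, with quantile normalisation 2666 rose and 2412 fell, and in the authors' values 2821 rose and 2407 fell. The 5 slides were also taken 1 at a time. In the planned comparison, after each strain's mid-level over all slides was removed, the regions that passed kept the sign of their mean change in 86.9% to 98.7% of cases, but the same samples had set that mean and the mid-levels. A comparison without this overlap was therefore set up after the data were seen. Regions called from the RNA samples of the other slides had the same sign in the arrays of the slide itself in 68.1% of cases on slide 1, 94.8% on slide 2, 97.8% on slide 3, 91.0% on slide 4 and 87.6% on slide 5, against 52.1% to 55.9% if the signs were independent. Only strains with both phases on a slide were used there, 4 on slide 2, 2 on slide 3 and 1 on each of the others. With slide as a block 4681 regions passed.

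The same comparison was made in each strain. The response was shared in part. Independent lists of the same lengths would share 0.72 rises and 0.047 falls, but the lists of the 6 strains were not independent. Every strain was tested with 1 estimate of the spread per region, and CIRM-BIA122 and CIRM-BIA472 were nearly alike on the arrays. Some excess was therefore built in, and its size is not read. In all 6 strains 245 regions rose and 233 fell. These counts were 397 and 506 without the 5 bright samples, 157 and 141 with slide as a block, 7 and 78 with normexp background correction, and 119 and 108 without CIRM-BIA123 cold replicate 1. With the array median 137 rose in all 6 strains, and in the authors' values 398 fell in all 6. Across regions, which are not independent replicates, the responses of pairs of strains correlated with r between 0.47 and 0.82, and between 0.64 and 0.86 without the bright samples. In CIRM-BIA482, which had no bright array, 3541 regions passed, 2129 higher and 1412 lower. Its cold arrays were dim, with median signals of 40.8, 71.5 and 60.9, against 122 to 188 on its growth arrays. What this does to its counts was not tested. In CIRM-BIA122 955 rose and 934 fell, and in CIRM-BIA123 589 rose and 580 fell. These 2 strains had only 2 samples in 1 of their groups, and falls led in both under the other scalings and in the authors' values. With the array median 891 rose and 959 fell in CIRM-BIA122, and 531 rose and 663 fell in CIRM-BIA123. With quantile normalisation the counts were 923 and 1068 in CIRM-BIA122 and 575 and 712 in CIRM-BIA123, and in the authors' values 1020 and 1197 in CIRM-BIA122 and 646 and 846 in CIRM-BIA123. Without the bright samples of the other strains 3360 regions passed in CIRM-BIA122 and 2598 in CIRM-BIA123. With slide as a block 790 regions passed in CIRM-BIA122, against 1889, and after normexp background correction 284 rose and 543 fell in CIRM-BIA482. In the authors' values 1748 rose and 1760 fell in CIRM-BIA482.

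In the 3 strains with bright arrays the counts and their balance moved when those arrays were left out and, as in other strains, with the scaling. The main fit shared 1 estimate of the spread over all groups. With only a strain's own samples 2666 regions passed in CIRM-BIA9, 1375 in CIRM-BIA472 and 1086 in CIRM-BIA118, against 4040, 3771 and 2458. In strains without bright arrays the counts rose instead, to 3212 in CIRM-BIA122, 2042 in CIRM-BIA123 and 4776 in CIRM-BIA482. The counts therefore do not rank the strains. In CIRM-BIA9 3025 regions rose and 1015 fell, against 1280 and 1285 without the 5 bright samples of all strains, and 1803 and 1871 with the array median. In CIRM-BIA472 2646 rose and 1125 fell, against 1393 and 1471 without those 5 samples and 1444 and 2179 with the array median. In CIRM-BIA118 1433 rose and 1025 fell, against 1068 and 1077 without its own bright sample, 1785 and 1716 without all 5, and 1082 and 1347 with the array median. In CIRM-BIA9 and CIRM-BIA472 the values without the 5 samples rest on 1 cold sample, assumed to vary like the other groups.

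**Figure D3:**
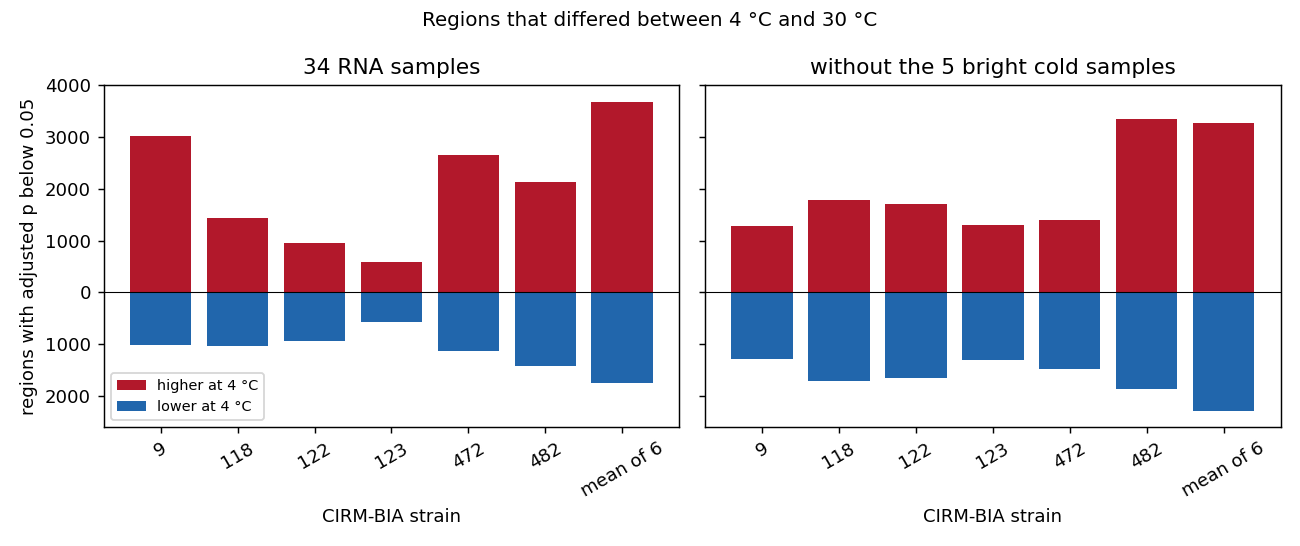
Number of target regions higher (red, upwards) or lower (blue, downwards) at 4 °C than at 30 °C at an adjusted p below 0.05, for each CIRM-BIA strain and for the mean of the 6 strains, with all 34 RNA samples (left) and without the 5 bright cold samples (right). In CIRM-BIA9, 3025 regions rose with all samples and 1280 without the bright ones.

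The strains were then compared in their response. The cold response of 1692 regions differed among the 6 strains (limma F test, adjusted over 7184 regions). Among these, 265 rose in at least 1 strain and fell in at least 1 other, of 271 such regions among all tested. Opposite calls were not counted under another scaling or without the bright samples, although the balance of rises and falls moved with both. The count of 1692 became 515 with the replicate block, 2802 in the authors' values and 4591 without CIRM-BIA472 cold replicate 3. Against the mean of the other 5 strains, CIRM-BIA482 differed at 728 regions, the most of the 6, and CIRM-BIA122 at 78, the fewest. The dim cold arrays of CIRM-BIA482 limit this comparison too. Without the bright samples CIRM-BIA482 again had the most, 2475, but CIRM-BIA9 had the fewest, 276, followed by CIRM-BIA472 with 284 and CIRM-BIA122 with 384. CIRM-BIA9 and CIRM-BIA472 then had 1 cold sample each, which lowers the number of regions that can pass, so these counts do not rank the strains. PFrdii_00041869 fell by 6.89 log2 units in CIRM-BIA482 and by 3.00 in CIRM-BIA118, and its response differed among strains in the main fit (limma adjusted p = 0.0115). Without the 5 bright samples 3284 regions differed in response, and with normexp background correction 52.

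Levels were compared among strains within each condition. At 30 °C 2294 regions differed among strains and at 4 °C 4972 (limma F test). With normexp background correction the counts were 792 and 1102. A random regrouping of the cold samples also reached a count above that of the real strains at 4 °C. The count at 4 °C is therefore no measure of how far the strains differ. The count at 30 °C was 4031 without the 5 bright cold samples, which leaves the growth samples as they were, and 1515 of 5479 regions with the stricter filter. The probes were designed on given sequences, so a lower level in a strain can also come from a mismatch or a missing sequence, and 472 of the regions that differed at 30 °C were not well above background on any growth array of at least 1 strain while well above it on every growth array of another. CIRM-BIA122 and CIRM-BIA472 differed at 69 regions at 30 °C, against 766 to 1370 in the other pairs. Without the bright samples they differed at 154 regions at 30 °C, against 1458 to 2542 in the other pairs. Their cold responses differed at 12 regions, and at 35 without the bright samples, against 125 to 890 and 319 to 2348 in the other pairs. At 4 °C they differed at 1387 regions, within the range of the other pairs (969 to 3047), and at 126 without the bright samples, against 967 to 4006.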

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

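Of the tests in this part, those of the slide, of the strain label and of a response shared by all cold cultures were chosen after the 5 bright arrays had been seen, and the fits without those samples were also added afterwards. The cold response of 1692 regions differed among strains by the test of the difference itself. In 99 reshuffles of the residuals of a model with strain and phase alone, on the regions without missing values, the highest count was 0. The real samples gave 1681 (1 of 100 as large, the real one included), which argues against a random order of the samples. The reshuffles spread the 5 bright arrays, which lay in the cold groups of 3 strains, over all groups. They therefore cannot tell a difference among strains from an effect of those arrays. In the main fit the responses of 3 of the 4 named regions also differed among strains, with limma adjusted p of 0.0417 for PFrdii_00185310, 0.0145 for PFrdii_00179079 and 0.0115 for PFrdii_00041869. The fit gave 0.0391 for PFrdii_00197342, but no difference among strains is read from it, since the change of this region is only bounded in CIRM-BIA123 and CIRM-BIA472. For single regions this difference was not examined without the bright samples or with normexp. The smallest rise of PFrdii_00185310, 2.86, was in CIRM-BIA472, a strain with bright arrays, so an effect of those arrays on its difference among strains is not excluded.

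Signals were high and compressed on 5 cold arrays of 3 strains, and the counts of differences among strains move with them. An effect of a slide on all its cold arrays is argued against, since 10 other cold arrays on the 3 slides concerned were ordinary. An effect on single arrays of a slide was not tested. A wrong strain label from outside the near-identical pair CIRM-BIA122 and CIRM-BIA472 is argued against, since all 5 arrays matched the ordinary cold arrays of their own strain or, for both arrays of CIRM-BIA472, those of CIRM-BIA122 best. For these arrays the mean r with CIRM-BIA122 was higher than with their own strain by 0.0139 and 0.0087, too little to decide, so an exchange within the pair stays open. A response of every cold culture of these strains is argued against, since 4 of their cold RNA samples were ordinary. Labelled material that does not depend on transcription, such as genomic DNA, would bring the 2 strands of a sequence closer together than a plain compression of the scale, but the ratio of strand partners to random regions, set against the strain's other arrays, ran from 0.83 to 1.06 (highest 1.055) and decides neither way. That explanation, RNA amount or quality, and a response of single cultures stay open.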

How the results depend on the processing

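Each probe by itself, the array median, the fits without the bright samples and the contrasts from the arrays of 1 slide alone were chosen after the data were seen. The changes of the 4 named regions kept their sign and passed under every alternative that gave a test, and kept their sign in the arrays of each slide alone, although those arrays also took part in choosing them (PFrdii_00185310 from 2.88 to 6.28, PFrdii_00179079 from -6.79 to -3.30, PFrdii_00041869 from -5.97 to -3.98). The planned within-slide contrasts, which used strain levels from all slides, ran from 3.05 to 4.30 for PFrdii_00197342, 3.29 to 5.22 for PFrdii_00185310, -5.91 to -4.24 for PFrdii_00179079 and -5.26 to -4.33 for PFrdii_00041869. For PFrdii_00197342 only the sign is read, since its change is only bounded in CIRM-BIA123 and CIRM-BIA472. PFrdii_00197342 had no value with the stricter filter. The count for the mean response stayed within 1.5 times of 5419 except with normexp (3556) and with each probe by itself (11177 of 14798 probes, where more features were tested). The cause of the other moves was not tested. With normexp 485 regions passed in CIRM-BIA9, 1519 in CIRM-BIA118, 644 in CIRM-BIA122, 332 in CIRM-BIA123, 1126 in CIRM-BIA472, 827 in CIRM-BIA482, 792 for levels at 30 °C, 1102 at 4 °C and 52 for the difference of responses. Normexp also turned the balance in CIRM-BIA9 (78 rose, 407 fell), CIRM-BIA482 (284 and 543), CIRM-BIA472 (464 and 662), CIRM-BIA123 (110 and 222) and CIRM-BIA122 (271 and 373), but not in CIRM-BIA118 (873 and 646). With each probe by itself 8237 probes passed in CIRM-BIA9, 4896 in CIRM-BIA118, 3711 in CIRM-BIA122, 2164 in CIRM-BIA123, 7666 in CIRM-BIA472, 7193 in CIRM-BIA482, 4643 at 30 °C, 9995 at 4 °C and 3311 for the difference of responses, while 425 rose and 416 fell in all 6 strains. With only a strain's own samples 2666 passed in CIRM-BIA9, 1086 in CIRM-BIA118, 3212 in CIRM-BIA122, 2042 in CIRM-BIA123 and 1375 in CIRM-BIA472. Without the bright samples 2565 passed in CIRM-BIA9, 3360 in CIRM-BIA122, 2598 in CIRM-BIA123, 4031 at 30 °C and 3284 for the difference of responses. With slide as a block 790 passed in CIRM-BIA122 and 2469 in CIRM-BIA472. The stricter filter, which tests 5479 regions, gave 1515 at 30 °C. The authors' values gave 2802 for the difference of responses. The replicate block gave 1212 in CIRM-BIA122, 678 in CIRM-BIA123 and 515 for the difference of responses, and 157 for regions that rose in all 6 strains. Whether the numbers pair the samples was not settled. The replicate block changed no other count by over 1.5 times.

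With each RNA sample left out in turn the counts ran from 5199 to 5665 for the mean response, 2746 to 4781 in CIRM-BIA9, 1814 to 2496 in CIRM-BIA118, 1014 to 1616 in CIRM-BIA122, 457 to 994 in CIRM-BIA123, 2539 to 4762 in CIRM-BIA472, 2682 to 3371 in CIRM-BIA482, 2067 to 2296 at 30 °C, 4121 to 6466 at 4 °C and 1141 to 4591 for the difference of responses. The last moved over 1.5 times without CIRM-BIA472 cold replicate 3 (4591), CIRM-BIA9 cold replicate 2 (3822) or CIRM-BIA118 cold replicate 3 (2873). In CIRM-BIA122 the count fell without growth replicate 2 (1014) or 3 (1062), and in CIRM-BIA123 without cold replicate 1 (457) or 2 (706), each leaving 1 sample in its group, assumed to vary like the others. Gene list tests and their alternatives were not run.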

Other observations

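The tests in this part were written before their results were seen, but the patterns themselves had been noticed in the data. CIRM-BIA122 and CIRM-BIA472 were nearly alike on the arrays. The smallest SD of the difference between a sample of each was 0.64 log2 units and the largest technical repeat SD 0.42. The 6 growth pairs ran from 0.64 to 0.72, and the 3 cold pairs without bright samples from 0.67 to 0.84. The 5 technical repeats ran from 0.27 to 0.42. All these pairs lay above the 5 repeats, which argues only against 1 RNA hybridised under both names for these samples. Replicates of a group without bright samples ran from 0.29 to 0.82. The values therefore do not tell 2 strains from separate cultures of 1 strain. Regions not well above background on any growth array of 1 strain and at least 16-fold higher on every growth array of another were counted. There were 0 for this pair and 71 to 135 for the other 14 pairs. So few were predicted if both strains have the same sequences under the probes. Smaller differences were not counted: PFrdii_00197342 was well above background on 2 of 2 growth arrays of CIRM-BIA122 and 0 of 3 of CIRM-BIA472. In CIRM-BIA122 453 regions were not well above background on any growth array, and in CIRM-BIA472 561. As a hypothesis, the 2 strains may be close relatives, and a culture carried under the wrong name stays open.

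In growth, 595 regions were not well above background on any array of at least 1 strain and well above it on every array of another. They lay side by side in the probe numbering: 32.8% were followed by another such region, against at most 12.4% in 10000 shuffles, which argues against a chance order, although neighbouring regions can belong to 1 gene. In the 2 bright cold arrays of CIRM-BIA9, the median of the 68 such regions dark in that strain, minus that of the 337 dimmest regions detected in its growth arrays, was -2.68 and -3.38 log2 units. The same difference was already -2.31 in the growth arrays on which the regions were chosen, past the bound of -1.5 set for the test, so the test decides nothing. This starting difference was checked only after the result was seen. Low or no expression, and a sequence missing from or altered in a strain, cannot be told apart here.

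Chance can be excluded for the count of the mean cold response as a whole, where the highest of the other splits of the samples within strains gave 4 regions against 5419 (1 of 100 as large). Those splits mix cold and growth samples in a group, which widens the spread. The 4 regions are therefore no estimate of the false calls among the 5419. For the count of levels at 30 °C chance can also be excluded, with 406 regions at most against 2294 (1 of 100). At 4 °C 2 of 100 splits, the real one included, gave at least 4972 regions, a share under 0.05, although the highest other gave 5156. Which samples that split put together was not examined. With 3 samples against 3 there are 10 splits, too few for a share under 0.05. The real split gave 4040 regions in CIRM-BIA9, 2458 in CIRM-BIA118, 3771 in CIRM-BIA472 and 3541 in CIRM-BIA482, and the highest other gave 0, 1, 2491 and 0.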
